A study of Mus musculus with 9 samples.

How the data were processed

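Total RNA from 9 samples of mouse salivary gland cancer stem cells was measured on Illumina mouse bead arrays, with 3 arrays for cells given the solvent DMSO, 3 for cells given ICG-001 and 3 for cells given LF3, each for 24 h. Per the labels' protocols, RNA was taken up in Trizol, cleaned on RNeasy columns with a DNase step and checked on a Bioanalyser, and biotin-labelled cRNA was made with a MessageAmp kit. GenomeStudio 2010.1 is named in the submitters' processing notes. Groups and replicate numbers were taken from the sample titles and treatment labels. The labels do not say whether the 3 replicates of a group were separate cultures, so every p-value measures only the spread between these samples, which may be technical. Doses are not given in the labels and are treated as unknown.

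The main table holds, per the file headers, a signal intensity and a detection p-value for each probe and array. The deposited intensities are on a linear scale, were not normalized between arrays, and had mean values per array from 340.0 to 467.3. The deposited detection p-values were below 0.01 for 9939 to 10897 of the 25697 probes per array, which is 38.7% to 42.4%. A second set of deposited values, the authors' processed intensities of the same arrays, is on a linear scale with negative values down to -17.5. Its normalization steps are not given in the sources used here. From the values, they look background-subtracted and quantile-normalized but not centred, with array medians of 9.3 to 9.4, and each array correlated best with its own signals (r from 0.974 to 0.996 over 6413 probes, against at most 0.805 for any other array). Intensity columns were matched to samples by their names. The detection p-value columns carry no sample name and were matched by their place, each directly after its sample's signal column. 0 columns were left unmapped.

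Probes were named from the platform annotation: 23978 of the 25697 probes had 1 gene symbol, 0 had several and 1719 had none, giving 16593 genes. Symbols can be old, and a gene without a named probe is not analysed here. Background was corrected with the normexp model using the detection p-values (neqc in limma 3.58.1, R 4.3.3), with an offset of 16, followed by log2 transformation and quantile normalization. Probes with a detection p-value under 0.01 on at least 3 of the 9 arrays were kept, which left 10830 probes (42.1%), 625 of them without a gene symbol. For each gene the probe with the highest mean over all 9 arrays stood for it, which gave 7354 genes. The offset shrinks fold changes of dim genes toward 0.

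All 9 arrays entered 1 limma fit (lmFit and eBayes, without trend), so that the 3 groups shared 1 estimate of the spread. The comparisons were LF3 minus DMSO, ICG-001 minus DMSO, LF3 minus ICG-001 and the F test among the 3 groups. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all probes kept, and a gene passed at an adjusted p under 0.05. Levels are normalized log2 intensities given as mean ± SD over the 3 arrays of a group. The median standard error of a log2 difference was 0.135, and the number of arrays limits the precision. A probe not detected on any array of one group has only a bound. Its fold is given as "at least", computed from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal. The same bound is given where 1 of 3 arrays of the dim group detected the probe.

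Lists of pathway genes and of cell type markers, 37 in all, were written before the data were examined, as were the design, the alternatives and the rule for named genes. The 35 lists with at least 5 measured genes were tested with limma's camera, which compares a list's genes with all other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the lists. The p with the correlation estimated from the data is given beside it. Beside the count of members that passed over all genes, the count with p-values adjusted over the list alone is given. Genes were named by a rule: the 8 largest rises and 8 largest falls against DMSO (the 5 largest each way between the inhibitors) among genes that passed with all arrays of a group outside the range of the other, the 4 members of each list with the lowest adjusted p, the 4 genes called in opposite directions by the inhibitors with the largest difference between them, and a fixed set of Wnt pathway genes. A few members of lists outside this rule were chosen after their values were seen and are said to be.

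On simulated data with 200 changed genes among 7354, differences of 1 and 2 on the log2 scale were recovered in 100% of cases in every comparison. A difference of 0.5 was recovered in 40.3% of cases for LF3 minus DMSO, 32.8% for ICG-001 minus DMSO and 38.8% for LF3 minus ICG-001, with 2.48%, 4.43% and 3.8% of calls false. In the data 22.4% to 39.7% of genes passed, a far larger share than was changed in the simulation. A larger share loosens the Benjamini-Hochberg cutoff, so these rates of recovery do not carry over to the data. For the overlap of the inhibitors, 100 sets of 9 unchanged arrays were simulated, DMSO included, with both treated groups compared with the same simulated DMSO arrays. The overlap was also counted again with a different single DMSO array for each inhibitor. Alternatives covered background correction, offset, normalization, the filter on dim probes, the authors' processed values, the variance model, array weights, the samples in the fit, the treatment of several probes per gene, a stricter threshold, the replicate number as a block, and leaving out each array. Figures were drawn from the same values.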

Results

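Gene expression was profiled in mouse salivary gland cancer stem cells (strain C57BL/6), isolated from primary material and cultured in medium with serum replacement, after 24 h with DMSO, LF3 or ICG-001. The series describes both compounds as Wnt inhibitors. LF3 is known to block the binding of β-catenin to TCF4, and ICG-001 to block the binding of β-catenin to the coactivator CBP. Each group had 3 bead arrays, 9 in all. Mean signal per array ranged from 340.0 to 467.3, and 9939 to 10897 of 25697 probes were detected per array. Normalized log2 intensities correlated at r = 0.9873 to 0.9942 between arrays of 1 group and at 0.9614 to 0.9835 between the 27 pairs of arrays from different groups. These correlations are across probes, which are not independent replicates. The residual SD was 0.191 on the first DMSO array and 0.193 on the third LF3 array, against 0.124 to 0.161 on the other 7. Across the 3 groups, 3845 of 7354 genes passed limma's F test.

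Vimentin (Vim), an intermediate filament of mesenchymal cells, stood at 12.66 ± 0.06 in DMSO (log2 intensity, mean ± SD, n = 3, as for all levels), and Slpi, a secreted protease inhibitor, at 13.51 ± 0.17. Aldh3a1, an aldehyde dehydrogenase used as a stem cell marker, stood at 14.22 ± 0.07. These 3 genes were chosen for this description after their values were seen. Most markers of differentiated epithelium were not detected on any array: 21 of 25 acinar markers on the array, 24 of 31 ductal and luminal markers, 13 of 21 basal markers and 28 of 36 squamous markers. The same held for 19 of 25 macrophage and leukocyte markers, 18 of 22 fibroblast markers and 13 of 19 endothelial markers. Some detected markers were bright, so these counts do not show a lack of acinar or ductal expression. On the DMSO arrays the acinar markers Aqp5, Xbp1 and Slc12a2 stood at 11.60 to 11.97, 10.21 to 10.56 and 10.27 to 10.36. The ductal marker Wfdc2 stood at 12.38 to 12.63, while Cldn7 stood at 5.07 to 5.32. Aqp5 fell by 0.72 under ICG-001 (limma adjusted p = 0.000401). Of 38 Wnt/β-catenin target genes on the array, 27 were not detected on any array, among them Axin2, a feedback inhibitor of the pathway, the transcription factor Lef1 and the receptor Lgr5. Only 10 could therefore be compared between groups. No probe used here was named for Crebbp, which encodes CBP.

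LF3 was compared with DMSO to ask what an inhibitor of the β-catenin/TCF4 interaction does to expression within 24 h. Ddit3, Fgf21 and Gsta4 were among the 8 largest rises. Ddit3, which encodes the stress transcription factor CHOP, was 7.87-fold higher (11.47 ± 0.20 against 8.50 ± 0.62, limma adjusted p = 2.63e-06), with the first DMSO array at 9.21 and the other 2 at 8.22 and 8.06. Fgf21, a secreted metabolic hormone induced by ATF4, was 4.59-fold higher (9.41 ± 0.13 against 7.22 ± 0.27). Gsta4, a glutathione S-transferase that detoxifies lipid peroxidation products, was 4.39-fold higher (9.38 ± 0.29 against 7.25 ± 0.21). At the preset correlation only, 4 lists were shifted downward: DNA replication (adjusted p = 0.0507 with an estimated correlation), cholesterol synthesis (adjusted p = 0.287), fatty acid synthesis (adjusted p = 0.247) and glycolysis with hypoxia (adjusted p = 0.287).

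In all, 1645 genes (22.4% of 7354) passed in LF3 minus DMSO, 810 higher and 835 lower, and 2650 had an unadjusted p under 0.05. The count rested on single arrays: it was 873 without the second DMSO array, 924 without the third DMSO array and 1027 without the second LF3 array. Median scaling in place of quantile normalization put the median of all genes at -0.24 on the log2 scale and left 203 genes higher and 2140 lower, whereas cyclic loess gave 797 and 851. Median scaling used all 25697 probes, of which 38.7% to 42.4% were detected per array, so it aligned signals near background. Mean signal was 340.0 to 396.5 on the LF3 arrays and 398.2 to 467.3 on the DMSO arrays. Calls that change under this setting should be read with that limit. At least 2-fold changes were found for 101 genes, 51 higher and 50 lower, and for 49 genes without background correction and 182 with median scaling. The 8 largest rises were Cox6a2, a muscle-type subunit of cytochrome c oxidase (8.67-fold, detected on 2 of 3 DMSO arrays), Ddit3, Fa2h, a fatty acid 2-hydroxylase (6.89-fold), Cdsn, the adhesion protein corneodesmosin (4.86-fold), Fgf21, Gsta4, the growth arrest gene Gadd45a (4.34-fold) and the RNA-binding protein gene Rbm15 (4.12-fold). The largest falls by fitted difference were Angptl4, an inhibitor of lipoprotein lipase (3.74-fold, adjusted p = 5.07e-06), the chemokines Cxcl12 (3.37-fold) and Cx3cl1 (3.08-fold), the plakin Ppl (3.05-fold, detected on 2 of 3 LF3 arrays), Rgcc, a cell cycle regulator gene (at least 2.19-fold, detected on 1 of 3 LF3 arrays), the clock and hypoxia repressor Bhlhe40 (2.8-fold), the glycosyltransferase Mgat3 (at least 1.73-fold) and Plvap, a protein of endothelial fenestrae (2.62-fold). The 2 other Cxcl12 probes gave -0.66 (adjusted p = 0.0238) and -0.58 (adjusted p = 0.0564) on the log2 scale, and a second Ppl probe gave 0.30 (adjusted p = 0.189).

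The list of amino acid response and ATF4 target genes was shifted upward under LF3 (median log2 change 0.35, camera adjusted p = 3.29e-05, adjusted p = 0.247 with an estimated correlation). Of its 39 measured members, 17 rose and 3 fell, and adjusted over the list alone 17 rose and 4 fell. Ppp1r15a, the phosphatase subunit that reverses the integrated stress response, rose by 1.71 on the log2 scale, and the cystine transporter Slc7a11 rose by 0.94. NRF2 target genes, which serve the antioxidant response, were also shifted upward (median 0.21, adjusted p = 3.29e-05, adjusted p = 0.0507 with an estimated correlation): 13 of 32 rose and 2 fell, and adjusted over the list alone 13 rose and 3 fell. Its leading members were the glutathione S-transferase Gsta4, the closely related pair Gsta1 (1.92) and Gsta2 (1.90) of the same family, and the sulfiredoxin Srxn1 (1.05). Hspa5, the endoplasmic reticulum chaperone BiP, rose by 1.19. The unfolded protein response list to which it belongs had 6 of 25 members higher and 0 lower and did not pass (median 0.16, adjusted p = 0.0743). It did pass without the third DMSO array (adjusted p = 0.0374), without background correction (0.0484), with an offset of 50 (0.0493) or with no filter on dim probes (0.025). Adjusted over the list alone, 6 were higher and 1 lower.

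Of 38 measured DNA replication genes, 17 fell and 0 rose (19 and 0 adjusted over the list alone), with a list median of -0.36 (camera adjusted p = 5.97e-06, adjusted p = 0.0507 with an estimated correlation). Both large and small subunits of ribonucleotide reductase, Rrm1 (-0.77) and Rrm2 (-0.77), the licensing factor Cdc6 (-0.65) and the replication initiation factor Mcm10 (-0.74, with -0.17 and adjusted p = 0.318 on a second probe) were among them. Genes of mitosis did not pass as a list (median -0.11, adjusted p = 0.286): 4 of 41 fell and 0 rose, with the same counts adjusted over the list alone. In cholesterol synthesis and uptake, 9 of 19 members fell and 0 rose (10 and 0 adjusted over the list alone; median -0.42, adjusted p = 0.00017, adjusted p = 0.287 with an estimated correlation), including the HMG-CoA synthase Hmgcs1 (-0.71), the sterol oxidase Msmo1 (-0.86) and the reductase Dhcr7 (-0.74). In fatty acid synthesis, 4 of 20 fell and 1 rose, with the same counts adjusted over the list alone (median -0.26, adjusted p = 0.0295, adjusted p = 0.247 with an estimated correlation). The elongase Elovl6 was at -0.79. The call of the fatty acid synthesis list ended without the first DMSO array (adjusted p = 0.0509) and without the second LF3 array (adjusted p = 0.0603). In the glycolysis and hypoxia list, 15 of 28 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.41, adjusted p = 1.5e-05, adjusted p = 0.287 with an estimated correlation). The members with the lowest adjusted p included Egln1 and Egln3 (both -1.03), prolyl hydroxylases that mark HIF-α for degradation, and the phosphofructokinase Pfkl (-0.81, with -0.01 on a second probe).

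The Wnt/β-catenin target list did not pass under LF3 (median -0.10, camera adjusted p = 0.494): 1 of 10 members rose and 1 fell, also adjusted over the list alone. Kremen1, a Dickkopf coreceptor, fell by 0.77 on the log2 scale (adjusted p = 0.00303). Sox9, a progenitor transcription factor, was at 0.51 (adjusted p = 0.0188), a call that median scaling ended at 0.29 and that leaving out the third DMSO array (0.41), the first LF3 array (0.45) or the second LF3 array (0.46) also ended. Cyclin D1 (Ccnd1) was at -0.37 (adjusted p = 0.0881), while its other probes gave -0.39 (adjusted p = 0.0404) and -0.60 (adjusted p = 0.00293), and leaving out the first DMSO array (-0.54, adjusted p = 0.0108) or 6 other settings also made it pass (adjusted p from 0.0164 to 0.0486). Cd44 (-0.30, adjusted p = 0.0692), Myc (0.32, adjusted p = 0.243) and Birc5, the apoptosis inhibitor survivin (-0.08, adjusted p = 0.651), did not pass. Myc did pass without the first DMSO array (0.60, adjusted p = 0.00416) and with array weights (0.46, adjusted p = 0.0342). Cd44 passed with median scaling (-0.59, adjusted p = 0.00642), without background correction (adjusted p = 0.0455), with an offset of 50 (0.0459) and with no filter on dim probes (0.0365). Ctnnb1, which encodes β-catenin, was at -0.29 (adjusted p = 0.206) and Ep300, the CBP paralog, at -0.34 (adjusted p = 0.119), and both passed with median scaling (-0.46, adjusted p = 0.0434, and -0.64, adjusted p = 0.00689). Tcf7l2, which encodes TCF4, was at -0.45 (adjusted p = 0.02), a call that ended without DMSO array 2 (adjusted p = 0.0751), DMSO array 3 (0.0756), LF3 array 2 (0.0617) or LF3 array 3 (0.0554). Of 24 Wnt pathway components, 4 rose and 6 fell (4 and 8 adjusted over the list alone; median -0.23, adjusted p = 0.322), among them the ligand Wnt5b (-0.68) and the β-catenin cofactor Bcl9l (-0.62), both lower.

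ICG-001 was compared with DMSO to ask the same of an inhibitor of the β-catenin/CBP interaction. Genes known for antiviral roles were among the largest rises. Rsad2, which encodes the antiviral enzyme viperin, was 12.8-fold higher (9.13 ± 0.87 against 5.45 ± 0.17, limma adjusted p = 1.12e-06), and Cxcl10, an interferon-induced chemokine, 8.68-fold higher (8.75 ± 0.70 against 5.64 ± 0.34, detected on 2 of 3 DMSO arrays). The list of mitosis genes was shifted downward (adjusted p = 0.0367 with an estimated correlation), with the mitotic kinase Plk1 2.1-fold lower (9.44 ± 0.11 against 10.51 ± 0.10), and p53 target genes upward (adjusted p = 0.0444 with an estimated correlation). In cholesterol synthesis, a list shifted downward at the preset correlation only (adjusted p = 0.0835 with an estimated correlation), farnesyl diphosphate synthase, Fdps, was 5.28-fold lower (9.31 ± 0.55 against 11.71 ± 0.27).

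In all, 2773 genes (37.7%) passed in ICG-001 minus DMSO, 1380 higher and 1393 lower, 382 of them at least 2-fold (188 higher and 194 lower, and 227 in all without background correction), and 3424 had an unadjusted p under 0.05. With median scaling 832 were higher and 1554 lower, and the median of all genes was -0.10. Rises and falls are ordered here by fitted difference, also where only a bound is known. The largest rises were Cdsn (12.8-fold), Rsad2, the oligoadenylate synthetase-like gene Oasl2 (11.9-fold), the ISG15 protease Usp18 (11.6-fold), Ifit3, an inhibitor of viral replication (9.37-fold), Cox6a2 (9.37-fold, with the same DMSO detection as above), the chemokine Ccl4 (at least 5.29-fold) and Cxcl10. The largest falls were Selenbp1, a selenium-binding protein gene (15.6-fold, 5.63 ± 0.20 against 9.60 ± 0.25, adjusted p = 1.44e-08), the receptor gene Mrgprf (at least 4.28-fold), the angiopoietin Angpt2 (at least 4.9-fold), the calcification inhibitor Mgp (at least 3.08-fold), Fdps, the hypoxia-induced carbonic anhydrase Car9 (5.07-fold), Asb2, which encodes a ubiquitin ligase subunit (5.0-fold), and Cxcl12 (4.96-fold).

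**Figure D1:**
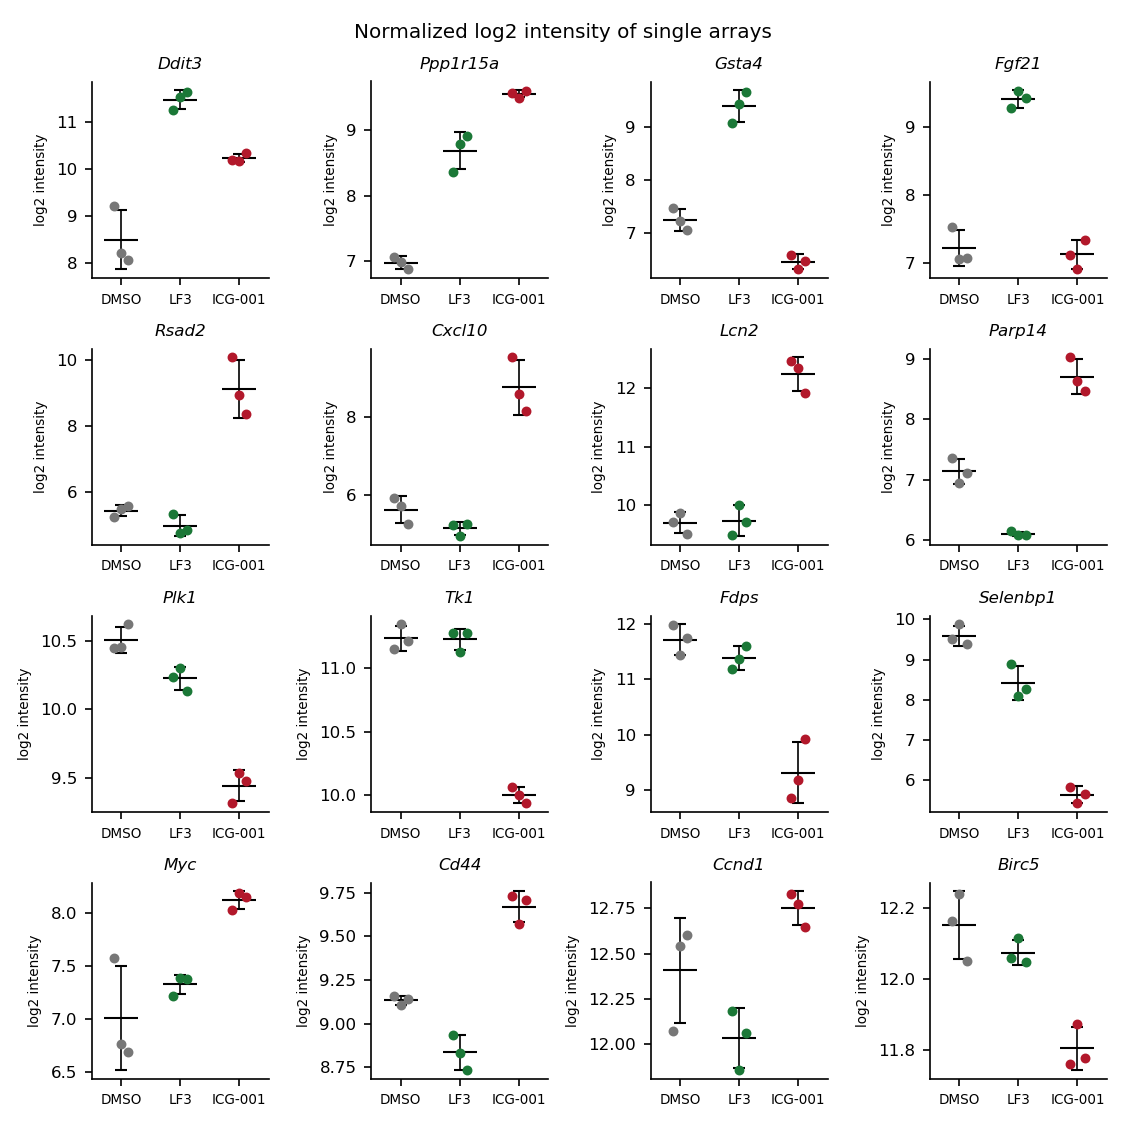
Normalized log2 intensity (vertical axis) of 16 genes on each array in DMSO, LF3 and ICG-001, where points are arrays and bars show the mean ± SD of 3 arrays. Ddit3 lies highest in LF3 (11.47), Rsad2 is high in ICG-001 alone among the 3 groups (9.13, against 5.45 in DMSO and 5.00 in LF3), and Plk1 is lowest in ICG-001 (9.44).

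Of 28 measured interferon-stimulated genes, 25 rose under ICG-001 and 0 fell (25 and 1 adjusted over the list alone), with a median of 1.42 (2.67-fold, camera adjusted p = 2.26e-13, adjusted p = 0.175 with an estimated correlation). The list had 43 genes on the array, of which 10 were detected on no array and 17 on all 9. A gene detected under ICG-001 alone entered the filter by being high there, so it could only rise. Oasl1 rose by 2.48, and Gbp3, an interferon-induced GTPase, was at least 6.39-fold higher. The 3 ICG-001 arrays differed in these genes: Rsad2 stood at 10.08, 8.94 and 8.36, and Ifit3 at 9.86, 8.73 and 7.95. Among 5 measured macrophage and leukocyte markers, 2 rose and 0 fell, with the same counts adjusted over the list alone (median 0.14, adjusted p = 0.34). These were Cd74, the invariant chain of MHC class II (at least 1.29-fold), and Cd14, an endotoxin receptor (0.59). Inflammatory cytokines and NF-κB target genes were shifted upward (median 0.58, adjusted p = 0.000276, adjusted p = 0.104 with an estimated correlation): 15 of 23 rose and 3 fell, also adjusted over the list alone. Lipocalin 2, Lcn2, which binds bacterial siderophores, was 5.82-fold higher, and the chemokine Ccl5 4.23-fold. Immediate-early genes were shifted upward too (9 of 21 rose and 1 fell, also adjusted over the list alone; median 0.30, adjusted p = 0.00165, adjusted p = 0.175 with an estimated correlation), with Klf2 at 2.18 and Junb at 0.93, while the growth factor signalling inhibitor Spred1 fell by 1.04.

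Under ICG-001, 28 of 41 mitosis genes fell and 0 rose (31 and 0 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 2.8e-10, adjusted p = 0.0367 with an estimated correlation). The phosphatase Cdc25c fell by 1.18 and the condensin subunit Ncapd2 fell by 1.13. Of 38 DNA replication genes, 23 fell and 0 rose (26 and 0 adjusted over the list alone; median -0.42, adjusted p = 2.11e-07, adjusted p = 0.0367 with an estimated correlation), including thymidine kinase Tk1 (-1.23) and DNA ligase Lig1 (-1.31, with -1.22, -0.81 and -0.25 on its 3 other probes, the last at adjusted p = 0.304). Of 30 p53 target genes, 15 rose and 3 fell, also adjusted over the list alone (median 0.36, adjusted p = 0.000323, adjusted p = 0.0444 with an estimated correlation). The polo-like kinase Plk2 rose by 1.81, the growth arrest gene Gadd45a by 2.38 and the apoptosis activator PUMA (Bbc3) by 1.02. ATF4 target genes had 18 of 39 members higher and 2 lower (19 and 2 adjusted over the list alone; median 0.27, adjusted p = 0.000323, adjusted p = 0.224 with an estimated correlation), with Ppp1r15a 5.97-fold higher.

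In cholesterol synthesis and uptake, 16 of 19 members fell under ICG-001 and 0 rose, also adjusted over the list alone, with a median of -0.92 (camera adjusted p = 1.68e-09, adjusted p = 0.0835 with an estimated correlation). Stard4, a sterol carrier, fell by 1.82 and Nsdhl by 1.79 on the log2 scale, and the isomerase Idi1, detected on 1 of 3 ICG-001 arrays, was at least 2.86-fold lower. In fatty acid synthesis, 13 of 20 fell and 2 rose, also adjusted over the list alone (median -0.45, adjusted p = 0.000323, adjusted p = 0.0444 with an estimated correlation), among them the desaturases Scd1 (-1.37) and Scd2 (at least 2.78-fold lower). In the glycolysis and hypoxia list, 18 of 28 fell and 1 rose (19 and 1 adjusted over the list alone; median -0.66, adjusted p = 1.33e-06, adjusted p = 0.192 with an estimated correlation), including the mitophagy receptor Bnip3l (-1.48) and Egln3 (-1.34). Selenbp1, which is not a glycolytic enzyme, belongs to this list as well. Ribosome biogenesis genes had 19 of 37 members higher and 0 lower, also adjusted over the list alone (median 0.38, adjusted p = 5.2e-05, adjusted p = 0.139 with an estimated correlation). Imp4, which takes part in processing of the small subunit RNA, rose by 1.42, and Pes1, which acts in large subunit assembly, by 1.05. NRF2 target genes moved both ways, 8 of 32 higher and 10 lower (8 and 11 adjusted over the list alone; median -0.09, adjusted p = 0.784), with isocitrate dehydrogenase Idh1 at -1.73 and the autophagy receptor Sqstm1 at 1.27. On the ICG-001 arrays Gsta1 stood at 9.77 to 10.32 against 9.13 to 9.32 in DMSO, and Gsta2 at 9.24 to 9.58 against 8.20 to 8.50. Gsta4 went the other way, at 6.34 to 6.60 against 7.06 to 7.47.

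Of 10 measured Wnt/β-catenin target genes, 3 rose and 4 fell under ICG-001 (4 and 4 adjusted over the list alone), and the list did not pass (median -0.11, camera adjusted p = 0.868). Myc was 2.17-fold higher (8.12 ± 0.08 against 7.00 ± 0.49, adjusted p = 0.000401), and Cd44, a hyaluronan receptor used as a stem cell marker, rose by 0.54 (adjusted p = 0.0019). Kremen1 fell by 0.90 and the homeobox gene Msx1 by 0.52. Birc5 was at -0.35 (adjusted p = 0.0227), a call that ended without DMSO array 2 (adjusted p = 0.0913), ICG-001 array 1 (0.0728) or ICG-001 array 3 (0.071) and on a second probe (0.0518). Ccnd1 did not pass (0.34, adjusted p = 0.0858), except without background correction (adjusted p = 0.0467), with an offset of 50 (0.0476) or with a trended, robust variance model (0.0314). Tcf7l2 fell by 0.64 (adjusted p = 0.0011), while Ctnnb1 was at -0.10 (adjusted p = 0.632) and Ep300 at 0.01 (adjusted p = 0.98). Of 24 Wnt pathway components, 4 rose and 9 fell (5 and 10 adjusted over the list alone; median -0.26, adjusted p = 0.274), among them Ctnnbip1, an inhibitor of the β-catenin/TCF interaction (-0.90), and the receptor Fzd2 (at least 1.66-fold lower).

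**Figure D2:**
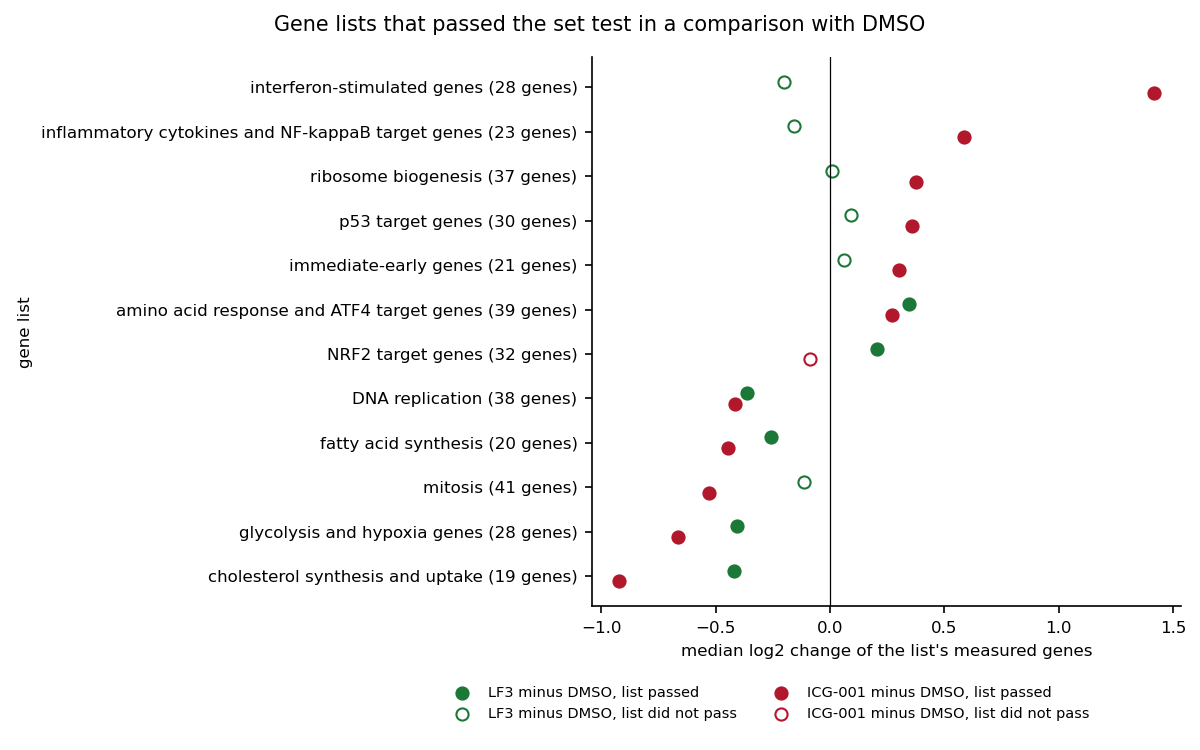
Median log2 change against DMSO (horizontal axis) of each gene list that passed the set test in at least 1 of the comparisons with DMSO, with filled points where the list passed at the preset correlation and open points where it did not (with an estimated correlation 0 lists passed under LF3 and 4 under ICG-001). Interferon-stimulated genes lie at 1.42 under ICG-001 and -0.20 under LF3, and cholesterol synthesis and uptake at -0.92 and -0.42, neither list passing with an estimated correlation.

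LF3 and ICG-001 were compared directly to ask where the inhibitors differ. Their doses are unknown, so differences in size between them cannot be put on a common scale of dose. The lists of mitosis genes and NRF2 target genes were shifted upward under LF3 relative to ICG-001 (adjusted p = 0.0493 with an estimated correlation for each), with Gsta4 7.51-fold higher (9.38 ± 0.29 against 6.47 ± 0.13, limma adjusted p = 5.59e-08). At the preset correlation only, the interferon-stimulated genes were shifted downward (adjusted p = 0.188 with an estimated correlation). Among them Usp18 was at least 13.2-fold lower (4.96 ± 0.31, detected on 1 of 3 LF3 arrays, against 9.13 ± 0.69, adjusted p = 2e-07).

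In the direct test, 2923 genes (39.7%) passed, 1489 higher and 1434 lower in LF3, 304 of them at least 2-fold. With median scaling 733 were higher and 1943 lower, and the median of all genes was -0.14. Of 28 interferon-stimulated genes, 23 were lower under LF3 and 0 higher (23 and 1 adjusted over the list alone; median -1.92, camera adjusted p = 5.34e-15, adjusted p = 0.188 with an estimated correlation). Members that the filter kept through the ICG-001 arrays alone could only come out lower here. Oasl2 was at least 12.6-fold lower, and Rsad2, detected on 1 of 3 LF3 arrays, at least 13.1-fold lower. Against DMSO, that list had 1 of 28 members higher and 4 lower under LF3, also adjusted over the list alone, and did not pass (median -0.20, adjusted p = 0.138, or 0.0495 without ICG-001 array 1), although the transcription factor Irf1 (-1.20) and the GTPase Gbp2 (-1.34) fell. Inflammatory and NF-κB target genes had 17 of 23 members lower and 3 higher (17 and 4 adjusted over the list alone; median -0.69, adjusted p = 1.86e-05, adjusted p = 0.0987 with an estimated correlation), with Lcn2 at -2.51. Against DMSO under LF3 the inflammatory list did not pass (4 of 23 higher and 9 lower, 6 and 9 adjusted over the list alone; median -0.16, adjusted p = 0.322), with Ptgs2, which makes prostaglandin precursors, at least 3.07-fold higher (detected on 1 of 3 DMSO arrays) and the acute-phase gene Saa3 at -1.14. The 5 macrophage and leukocyte markers passed as a list (3 lower and 0 higher, 4 and 0 adjusted over the list alone; median -0.51, adjusted p = 0.0474, adjusted p = 0.188 with an estimated correlation). That call ended without DMSO array 1 (adjusted p = 0.0515), DMSO array 3 (0.0508), LF3 array 1 (0.0561) or LF3 array 3 (0.0813), and in 10 settings in all.

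Of 41 mitosis genes, 26 were higher under LF3 than under ICG-001 and 0 lower (30 and 0 adjusted over the list alone; median 0.44, camera adjusted p = 7.93e-08, adjusted p = 0.0493 with an estimated correlation), for example Plk1 (0.79) and Cdc25c (1.34). DNA replication genes did not pass (11 of 38 higher and 4 lower, 11 and 5 adjusted over the list alone; median 0.13, adjusted p = 0.196), although Tk1 was higher under LF3 (1.23). NRF2 target genes had 18 of 32 members higher and 2 lower, also adjusted over the list alone (median 0.40, adjusted p = 9.47e-05, adjusted p = 0.0493 with an estimated correlation), including the quinone reductase Nqo1 (1.26) and the pentose phosphate enzyme transketolase, Tkt (1.46). Cholesterol genes had 12 of 19 higher and 1 lower (13 and 1 adjusted over the list alone; median 0.46, adjusted p = 0.000227, adjusted p = 0.212 with an estimated correlation), with Fdps at 2.07. Fatty acid synthesis had 9 of 20 higher and 1 lower, also adjusted over the list alone (median 0.23, adjusted p = 0.0321, adjusted p = 0.185 with an estimated correlation), a call that ended without the third LF3 array (adjusted p = 0.0526) and on probes detected on all 9 arrays (adjusted p = 0.0863). Ribosome biogenesis genes had 13 of 37 lower under LF3 and 1 higher, also adjusted over the list alone (median -0.27, adjusted p = 0.000257, adjusted p = 0.188 with an estimated correlation), led by Pes1 (-2.31). Against DMSO under LF3 that list did not pass (2 of 37 higher and 4 lower, 1 and 4 adjusted over the list alone, median 0.01, camera adjusted p = 0.997). Pes1 itself was lower on the LF3 arrays (6.64 to 7.18) than on the DMSO arrays (8.11 to 8.36), and Ncl fell by 0.78 under LF3. P53 target genes had 13 of 30 lower and 5 higher (14 and 5 adjusted over the list alone; median -0.26, adjusted p = 0.0297, adjusted p = 0.179 with an estimated correlation), with Plk2 at -1.11, a list call that ended when only probes detected on all 9 arrays were kept (adjusted p = 0.0863). ATF4 target genes did not pass in the direct test (8 of 39 higher and 10 lower, also adjusted over the list alone; median -0.07, adjusted p = 0.758), nor did the glycolysis and hypoxia list (9 of 28 higher and 4 lower, also adjusted over the list alone; median 0.27, adjusted p = 0.0583). The latter list did pass with median scaling (adjusted p = 0.0187), with cyclic loess (0.0499), with no filter on dim probes (0.0248), without ICG-001 array 1 (0.0288) or without LF3 array 2 (0.0277).

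Members of the Wnt/β-catenin target list differed between the inhibitors in both directions: 3 of 10 were higher and 4 lower under LF3 (4 and 4 adjusted over the list alone). The list did not pass (camera direction downward, adjusted p = 0.912), and its median of 0.09 and mean of -0.08 had opposite signs. Ccnd1 was lower under LF3 than under ICG-001 (-0.72, adjusted p = 0.0019), as were Myc (-0.80, adjusted p = 0.00413) and Cd44 (-0.84, adjusted p = 7.34e-05), whereas Sox9 (0.73, detected on 2 of 3 ICG-001 arrays) and Msx1 (0.68) were higher. Birc5 did not pass (0.27, adjusted p = 0.0641), but did on a second probe (0.35, adjusted p = 0.0441) and in 4 other settings (adjusted p from 0.0218 to 0.0353). Wnt pathway components had 3 of 24 higher and 1 lower, also adjusted over the list alone (median 0.09, adjusted p = 0.673).

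The inhibitors also moved many genes alike. Of 859 genes that passed against DMSO under both, 733 (85.3%) moved in the same direction, 366 up and 367 down, and 126 in opposite directions. Cox6a2, Cdsn, Ddit3, Fa2h and Gadd45a rose under both, and Selenbp1, Cxcl12 and Ppl fell under both, the last of these on its brighter probe. Independent lists of these sizes would share 152 rises and 158.2 falls, and 310.1 genes in opposite directions. Both comparisons use the same DMSO arrays. In 100 simulations of 9 unchanged arrays, DMSO included, the comparisons shared at most 0 genes in the same direction. Unchanged groups give few calls to share or none, so this value does not measure what shared controls add, and it leaves out any effect of the inhibitors. The count of 733 fell to 383 without the second DMSO array and to 421 without the third, where independent lists would share 128.4 and 144. The log2 changes correlated across genes at r = 0.398 (Spearman's rho 0.354), below the 0.501 that the simulated unchanged groups gave from sharing simulated DMSO arrays. Their covariance was 0.0734 against a simulated 0.0103, a difference of 0.0631. With 3 DMSO arrays the controls cannot be split into parts of 2, so part or all of the excess may come from the shared controls. With a different single DMSO array for each inhibitor, so that no array was shared, 118 to 277 genes moved in the same direction over the 6 choices. That was 2.39 to 4.01 times the count of independent lists, and the covariance was 0.0362 to 0.0916. Each lone array was assumed to vary like the treated groups, and this test was chosen after the overlap was seen. A deviation common to all 3 DMSO arrays would remain in it, so it cannot exclude the shared control as the whole cause. Of the 733 genes, 462 (63%) had the larger change under ICG-001.

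Of the 126 genes called in opposite directions, 66 were higher under LF3 and 60 higher under ICG-001. All 126 also passed in the direct test, which followed from their selection in the same fit and adds no support. Gsta4 rose under LF3 (2.13) and fell under ICG-001 (-0.78), and Parp14, an interferon-induced ADP-ribosyltransferase, fell under LF3 (-1.04) and rose under ICG-001 (1.57). Dbp, a clock output transcription factor, was at 0.60 under LF3, a call that median scaling ended at 0.31, and at -1.93 under ICG-001. Cmpk2, a mitochondrial nucleotide kinase induced by interferon, was at least 3.52-fold higher under ICG-001 (detected on 1 of 3 DMSO arrays). Its place among the 126 rests on a call under LF3 (adjusted p = 0.0436) within the background, since 1 DMSO array and 0 LF3 arrays detected it, so its direction under LF3 was not measured. Leaving out DMSO array 2 (adjusted p = 0.164), DMSO array 3 (0.104), ICG-001 array 2 (0.0519) or any 1 LF3 array (0.0586 to 0.117) ended that call.

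**Figure D3:**
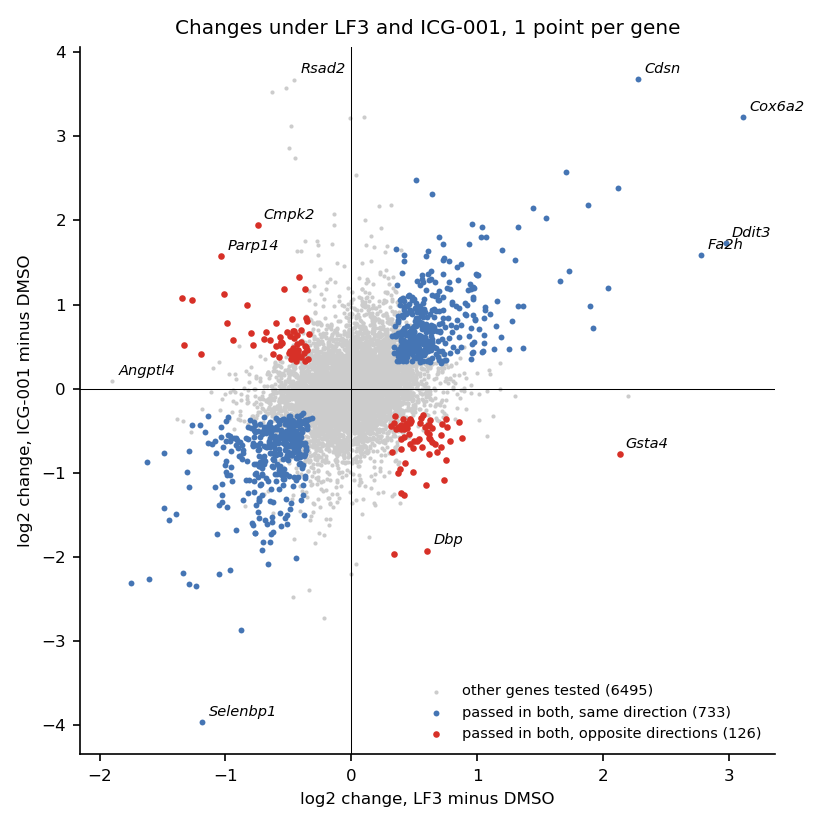
Log2 change under LF3 (horizontal axis) against log2 change under ICG-001 (vertical axis), both relative to DMSO, with 1 point for each of 7354 genes. Blue points mark the 733 genes that passed in both comparisons in the same direction and red points the 126 that passed in opposite directions. The interferon-stimulated gene Rsad2 lies far up the vertical axis and left of 0 on the horizontal axis, with 1 of 3 LF3 arrays detecting it.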

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

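Of the tests given here, those on the interferon-stimulated genes and, apart from the splits of the samples, those on the overlap between inhibitors were chosen only after the result was seen. Genes were picked out because they were called in opposite directions under the inhibitors, and probes because they carry no gene name and enter no gene count. For such genes a pass in the direct test follows from the selection and adds no support.

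Gsta4 differed by 2.91 on the log2 scale between LF3 and ICG-001, and Dbp by 2.53, both higher under LF3. Parp14 differed by -2.61, lower under LF3. Cmpk2 was not detected on any LF3 array and was at least 3.41-fold lower there than under ICG-001, so its fitted difference of -2.69 is not a measured size, and its direction under LF3 against DMSO was not measured. Of 625 measured probes with no gene name, 160 (25.6%) passed in LF3 minus DMSO, 93 higher and 67 lower. In ICG-001 minus DMSO 227 (36.3%) passed, 112 higher and 115 lower, and in LF3 minus ICG-001 267 (42.7%) passed, 147 higher and 120 lower. Their transcripts are not analysed here.

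The rise of interferon-stimulated genes under ICG-001 (adjusted p = 0.175 with an estimated correlation, so the list call holds at the preset one only) had 2 technical explanations to weigh. Leukocytes in the ICG-001 cultures alone would bring their own transcripts, yet of 21 leukocyte markers undetected on all DMSO arrays the ICG-001 arrays all detected 1 (Cd74, 4.8%), which is itself induced by interferon in many cells. Only markers absent under DMSO were counted, so this test cannot exclude leukocytes present in every culture. The marker Laptm5 stood at 12.11 to 12.30 on the DMSO arrays, while 19 of 25 markers were detected on no array. Another background correction or normalization did not remove the shift, whose lowest median over 5 settings was 1.10. The labels record no chip or culture day, so a batch was not tested here or for the other patterns. A response of the cells to ICG-001 stays open as a hypothesis, and the spread of these genes between the 3 ICG-001 arrays was not explained.

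The NRF2 list call under LF3 holds at the preset correlation only (adjusted p = 0.0507 with an estimated correlation), and the p-values that follow use the preset one. Signal shared between probes of related glutathione S-transferases could produce an apparent group shift, but without those 5 genes the median of the remaining 27 was 0.196 on the log2 scale (limma's camera, unadjusted p = 0.000329). Without the 1 gene shared with the ATF4 list, the median of 31 genes was 0.201 (limma's camera, unadjusted p = 1.52e-05). Leaving out 1 gene could hardly move the median, so the outcome of this second test was fixed by how little the lists share. These tests were laid down before their results were seen. They leave a response to LF3 open and did not measure one.

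The overlap in the same direction could come from 1 DMSO array that stands apart, but with any 1 DMSO array left out it was at least 383 genes, against 128.4 for independent lists. Chance values that differ between single DMSO arrays, as the whole cause, would leave no excess once each inhibitor has its own DMSO array. The count was then at least 2.39 times that of independent lists. A chance deviation common to all 3 DMSO arrays, as replicates of 1 culture could have, would stay in this test. It therefore cannot exclude the shared control as the whole cause. Of 100 splits of the 9 arrays into 3 groups, 2 gave an overlap of 733 or more, the real one included, and the other gave 1220. In that split the 3 ICG-001 arrays stood as the control and the DMSO and LF3 arrays were mixed over the other groups, so both of its comparisons hold the change under ICG-001. Mixed groups also break up effects of 1 inhibitor alone, and the real groups with an inhibitor as control were not drawn. The share of splits therefore cannot tell whether the inhibitors have effects in common, nor exclude the shared controls as a cause. Effects common to both inhibitors stay open as a hypothesis beside a handling difference between DMSO and treated cultures, which was not tested.

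Other splits of the samples were run for each count. For the F test, 1 of 100 splits reached the real 3845 genes, the real one itself, and the highest other gave 1448, so a random division of these arrays can be excluded. Since the replicates of a group may come from 1 culture, the splits cannot exclude chance differences between cultures. The correlation of 0.398 was reached or exceeded by 72 of 100 splits, with 0.936 the highest other. Every split shares a control, and simulated unchanged groups with a shared control gave 0.481 to 0.524, already above 0.398. Many splits also put effects of an inhibitor into the control. This share of splits therefore cannot tell whether the correlation arose by chance. Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. For LF3 minus DMSO the real counts were 1645 genes, 101 at least 2-fold and 6 lists, and the highest of the other splits gave 0, 0 and 4. For ICG-001 minus DMSO they were 2773, 382 and 11 against 0, 0 and 10, and for LF3 minus ICG-001 2923 genes and 9 lists against 0 and 6.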

How the results depend on the processing

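None of the alternatives given here was chosen only after the results were seen. Among 9578 values of named genes under the alternatives, 361 lost the threshold, 202 gained it and 10 changed sign with a call on at least 1 side. The other 9005 kept their side of the threshold, and changes of sign where neither value passed are counted among these. Among 2085 values of gene lists, 2051 were unchanged in this sense, 15 lost the threshold, 19 gained it and 0 changed sign with a call on either side. The 10 sign changes all came from another probe of the gene, in LF3 minus DMSO for Ppl (0.30), Itga5 (-0.014), Cald1 (-0.048), Tnfrsf10b (-0.059) and Actb (1.16, 1.04 and 1.00), in ICG-001 minus DMSO for Ppl (0.12), and in LF3 minus ICG-001 for Sars (-0.69) and Egfr (0.004). The cause was not tested. Leaving out 1 array at a time gave 873 to 1864 genes for LF3 minus DMSO (924 without the third DMSO array, 1027 without the second LF3 array), 2163 to 2953 for ICG-001 minus DMSO, 2275 to 3131 for LF3 minus ICG-001 and 3192 to 4073 for the F test. It gave 98 to 150 and 361 to 412 genes changed at least 2-fold under LF3 and ICG-001, 383 to 860 in the same direction (421 without the third DMSO array), a correlation of 0.37 to 0.459, and 5 to 8, 11 to 11 and 7 to 10 lists. The cause of these differences between arrays was not tested. A threshold of 0.01 gave 686, 1755 and 1854 genes. With an estimated correlation 0, 4 and 2 lists passed. At least 2-fold counts under LF3 were 49 without background correction, 51 with an offset of 50, 182 with median scaling and 66 with the authors' processed values, and under ICG-001 227 and 226 for the first 2 of these, where a larger floor shrinks the folds of dim genes by construction. Array weights gave a correlation of 0.423. With median scaling 1036, 2202 and 2155 of the genes remained called in LF3 minus DMSO, ICG-001 minus DMSO and LF3 minus ICG-001. The leukocyte list in LF3 minus ICG-001 lost its call in 10 settings. Whether the replicate numbers pair the samples is not given in the labels and was not settled. Over 9 pairs of arrays with the same number, deviations from the group means correlated at -0.233 to 0.143, 2 of them over 0.1. DMSO array 1 and LF3 array 2, which differ in number, reached 0.339, and the cause was not tested. With the replicate block, 1464, 2645 and 2797 genes passed, 1429, 2594 and 2744 of them among the genes called without it, and 6, 11 and 9 lists passed. A block for the bead chip was not run, since the files name the chip of 0 arrays. Signal over background limits the dim genes: 14867 probes did not pass the detection filter and were compared only where that filter was left out.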

Other observations

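The gene lists given here were written before the data were examined, and no test in this part was chosen only after its result was seen. Several groups that did not pass as lists held members with large changes. Among 14 measured TGF-β and BMP target genes, 3 rose and 4 fell under LF3 and 5 rose and 2 fell under ICG-001, with the same counts adjusted over the list alone (camera adjusted p = 0.876 and 0.441). Inhba, the activin βA subunit, rose by 1.88 under LF3 and by 2.18 under ICG-001, Grem1, a secreted BMP antagonist, was at least 1.83-fold and at least 2.75-fold higher, and Id2, a BMP-responsive inhibitor of differentiation, fell by 0.77 and by 1.72. In the extracellular matrix list, 5 of 22 rose and 7 fell under ICG-001, also adjusted over the list alone (adjusted p = 0.398), against 1 and 3 under LF3 (3 and 4 adjusted over the list alone, adjusted p = 0.38). The basement membrane collagens Col4a1 (-1.30) and Col4a2 (-1.13) and collagen VI, Col6a1 (-1.40), fell under ICG-001, and tenascin C, Tnc, was at least 2.78-fold higher (detected on 1 of 3 DMSO arrays). In the direct test Col4a1 was higher (1.12) and Tnc at least 2.48-fold lower (detected on 1 of 3 LF3 arrays) under LF3 than under ICG-001. Among 13 stem cell genes, 6 rose and 2 fell under ICG-001, also adjusted over the list alone (adjusted p = 0.362), with Klf5 at 1.05, Klf4 at 0.81 and Cd34 at 0.96, all transcription factors or surface markers of progenitor cells, and Aldh3a1 at -1.09. Under LF3 2 rose and 1 fell (2 and 3 adjusted over the list alone, adjusted p = 0.876).

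Of 55 oxidative phosphorylation genes, 5 rose and 10 fell under ICG-001, also adjusted over the list alone (median -0.06, limma camera adjusted p = 0.34), with the complex III subunit Uqcrh at -1.32 and the cytochrome oxidase subunit Cox7a2 at -1.07. Under LF3, 2 rose and 2 fell (1 and 2 adjusted over the list alone; median 0.08, adjusted p = 0.424). In the direct test 16 of 55 were higher and 3 lower under LF3 (15 and 3 adjusted over the list alone; median 0.09, adjusted p = 0.0632, adjusted p = 0.205 with an estimated correlation). The list did pass with median scaling (adjusted p = 0.0187), with cyclic loess (0.0499), with no filter on dim probes (0.0164) or without LF3 array 1 (0.0448). Cox6a2, a subunit outside that list, was among the largest rises under both compounds. Squamous markers were mostly undetected, and the 5 measured moved both ways. Under LF3 1 rose and 1 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.997). Under ICG-001 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.868). Among them corneodesmosin, Cdsn, rose 4.86-fold under LF3 and 12.8-fold under ICG-001, and it differed by -1.40 in the direct test. Of 12 YAP target genes, 4 rose and 4 fell under ICG-001, also adjusted over the list alone (adjusted p = 0.949), with Ankrd1, a stress-responsive ankyrin repeat gene, at 1.04. Of 24 apoptosis genes, 5 rose and 2 fell under ICG-001, also adjusted over the list alone (adjusted p = 0.381), including the death receptor Fas (1.20) and the inflammatory caspase Casp4 (at least 2.29-fold). In the direct test 8 of 24 were lower and 2 higher under LF3 (8 and 3 adjusted over the list alone, adjusted p = 0.267).

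Of 12 measured genes often used as references, 1 rose and 3 fell under ICG-001 (0 and 3 adjusted over the list alone; median -0.09, adjusted p = 0.441). Rpl13a was at -1.36 and Eef2 at -0.86, and both fell under median scaling too (-1.42 and -0.92). Under LF3 1 rose and 2 fell, also adjusted over the list alone (median 0.01, camera direction downward, adjusted p = 0.997). Rplp0 was at 0.52 (adjusted p = 0.00638), a call that ended with median scaling (0.30, adjusted p = 0.154) and on a second probe (0.62, adjusted p = 0.0612). Gusb was at -0.45 (adjusted p = 0.0109), a call that ended without DMSO array 3 (adjusted p = 0.0533) and on 1 of 2 other probes (0.0891). Tfrc was at -0.43 (adjusted p = 0.0142), a call that ended without DMSO array 2 (adjusted p = 0.0535) and on a second probe (0.142). The brightest Actb probe did not pass (-0.32, adjusted p = 0.09), while of 4 other Actb probes 3 gave 1.16, 1.04 and 1.00 and the fourth -0.056 (adjusted p = 0.868). The brightest one passed with median scaling (-0.46, adjusted p = 0.0346) and in 3 other settings (adjusted p from 0.0274 to 0.0495). The cause of this difference between probes of 1 gene was not tested.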
